A study of Rattus norvegicus with 9 samples.

How the data were processed

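Bulk RNA-seq was deposited for 9 libraries of ventricular cardiomyocytes isolated from rats of the HXB23 strain, a recombinant inbred line, at postnatal day 0. The cells had been transduced for 48 hours with a vector that encoded green fluorescent protein (GFP), the 1073G variant of Shroom3 or the 1073S variant of Shroom3, with 3 libraries in each group. Total RNA was isolated with TRIzol and libraries were made with the Takara SMART-Seq mRNA LP kit. The labels disagree on the vector: the series design and the treatment labels name adenovirus, and the treatment protocol names AAV, an adeno-associated virus.

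The deposited file of each library held 1 line per transcript with the columns of a salmon quantification. Per the file headers, the column used throughout held estimated reads, that is expected counts, as the authors' salmon run assigned them to RefSeq transcripts. The effective length of each transcript, another deposited column, served only as an offset in 1 alternative. The deposited TPM values, which correct for transcript length, entered the tests only as weights when those lengths were averaged per gene. Per the submitters' processing notes, the upstream tools were FastQC 0.12.1, Trim Galore 0.6.10, STAR 2.7.10a, Salmon 1.10.3 and DESeq2 1.44.0 with the rat genome build mRatBN7.2. The notes give neither the role of each tool nor the annotation release.

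Each file listed 99257 transcripts. Their accessions, without the version, were matched to a RefSeq gene table of a later rat assembly, GRCr8, so no coordinates are given. Of these transcripts, 71528 (72.1%) matched a gene, 25891 had an accession that the table does not hold, and 1838 carried no accession. The matched transcripts belonged to 29418 genes and held 89.5% to 90.6% of the reads of each library. Unmatched accessions held 6.84% to 7.26% and names without an accession held 2.29% to 3.61%. The latter share followed the groups, at 3.46 ± 0.186% in GFP, 2.78 ± 0.133% in 1073G and 2.50 ± 0.189% in 1073S (mean ± SD, n = 3 each), and did not overlap between GFP and either variant. Estimated reads were summed per gene and rounded. Library totals ran from 68472332 to 108236579 reads. A count of 0 in a library was read as up to 3 counts, which is 0.0310 to 0.0486 CPM, and this floor covers counting error only, since reads from amplified libraries are not independent molecules.

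Genes were tested in edgeR 4.0.16 under R 4.3.3. All 9 libraries entered 1 fit with 1 coefficient per group, with TMM scaling, the filterByExpr filter by group, a robust quasi-likelihood fit and two-sided quasi-likelihood tests. The filter kept 15152 genes. P values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Comparisons were 1073G against GFP, 1073S against GFP, 1073S against 1073G, and the mean of both variants against GFP. The direct comparison of the variants also served as the test of whether their effects against the shared GFP libraries differed. Levels are CPM, the counts of a gene scaled to TMM-adjusted library sizes of equal total, given as mean ± SD, and fold changes are log2 values from the fit, given with their standard error where full statistics are printed.

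Before the data were examined, 34 gene lists with 554 entries (545 different genes) were fixed for this tissue and treatment, together with the comparisons, the tests, the alternatives and the rule for naming genes. Of the list entries, 14 matched no gene in the table and 7 matched a gene without a matched transcript. Lists with at least 5 tested genes were compared with all other genes by camera in limma 3.58.1 on voom values, with the preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 33 lists tested. The list of mitochondrially encoded genes could not be tested, because none of its genes had a matched transcript. Calls of single genes are also counted as adjusted over the list alone. Set tests with a correlation estimated for each list, and fry, which does not compare a list with other genes, were run beside it. 6 further lists with 96 entries were added after the fold changes were seen and are used only in the closing section. Their p values were adjusted over these 6 lists alone, so they are not comparable with values adjusted over the 33 lists.

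The rule for names was as follows. Shroom3 was named first. In each comparison of groups, the 10 largest rises and 10 largest falls were eligible among genes with a symbol, an adjusted p under 0.05, at least 1 CPM in the higher group and no overlap between the libraries of the groups. For each list with a called member, up to 3 called members with the smallest adjusted p were eligible. Of the lists tested, 1 is not reported here, and neither are 3 eligible genes. Genes that the text names outside this rule are marked where they appear. Every gene named under it had all 3 libraries of the higher group above all 3 of the lower group.

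The fit was tested on simulated data with the measured means and spreads. With 3 libraries per group it called 44% of genes changed 1.3-fold, 74% of genes changed 1.5-fold and 100% of genes changed 2-fold or 4-fold, with 8 false calls among 14727 unchanged genes. The list test called the 1 list that was shifted by 0.4 (log2) and none of the others. Simulated genes were drawn independently of each other, so this run cannot show false list calls that come from correlated genes. No 2 libraries were copies of each other: the chi-square per degree of freedom between replicates ran from 15.6 to 31.5. Correlations of log2 values between replicates were 0.981 to 0.986. Replicate numbers did not pair libraries across groups, so no block was used.

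The alternatives fixed beforehand were DESeq2 1.42.0 with its own size factors and filter, DESeq2-type size factors in edgeR, no filter on low counts, an offset for transcript length, the replicate number as a block, a fit of only the groups compared, leaving out each of the 9 libraries in turn, and for lists the estimated correlation and fry. After seeing the data, 1 alternative was added, in which each unmatched accession stayed in the fit as its own feature. Matching and figures were made in Python 3.11.15 with numpy 2.4.6. Overlap of the calls of both variants was set beside 20 simulated datasets with unchanged groups and the same shared controls.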

Results

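Gene expression was measured by RNA-seq in 9 libraries of neonatal rat ventricular cardiomyocytes, 3 after a GFP control vector, 3 after the 1073G variant and 3 after the 1073S variant of Shroom3, a regulator of actomyosin contraction. The series title names cardiomyocyte ploidy and Shroom3, so the comparisons ask which genes followed each variant. Library totals ran from 77689419 to 108236579 reads in GFP, 68472332 to 79109160 in 1073G and 73532649 to 82519998 in 1073S. The labels do not say whether the libraries of a group came from separate cultures, so p values measure only the spread between these libraries.

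Shroom3 was higher with both variant vectors than with GFP, as the labels require. Which variant a library carried was not checked, since counts per transcript do not show it. It stood at 40.1 ± 2.29 CPM (counts scaled to equal library totals) in GFP, 1197 ± 99.7 in 1073G and 5261 ± 425 in 1073S (mean ± SD, n = 3 libraries each). The log2 fold change against GFP was 4.90 ± 0.08 (SE) in 1073G (adjusted p = 3.1e-12) and 7.04 ± 0.09 in 1073S (adjusted p = 1.2e-13). Between the variants Shroom3 itself differed by 2.14 ± 0.07 (adjusted p = 1.2e-08), so that variant and level changed together in every comparison of 1073S with 1073G. The first component of all genes held 33.6% of the variance and placed GFP at -46.4 to -38.5, 1073G at 2.34 to 6.76 and 1073S at 35.5 to 39.7. The second held 11.7% and placed 1073G, at 20.5 to 24.97, outside both GFP (-13.5 to -2.19) and 1073S, whose libraries spread from 4.82 (replicate 1) over -11.5 to -35.7 (replicate 3).

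**Figure D1:**
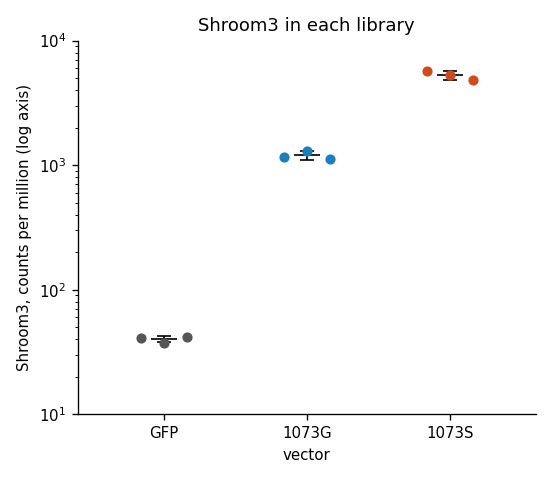
Shroom3 level on a log axis in CPM for each library, by vector; points are libraries, and bars give the mean ± SD of 3. The 3 GFP libraries sit at 37.4 to 41.5, the 3 of 1073G at 1119.9 to 1309.8 and the 3 of 1073S at 4833 to 5683.

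In 1073G against GFP, genes of cell division and of the p53 response rose together. Ccnb1, the cyclin that drives entry into mitosis, went from 248 ± 13.2 to 397 ± 18.3 CPM (n = 3 libraries each, log2 fold change 0.68), and the mitotic kinase Aurka (0.71) and the spindle protein Hmmr (0.63) rose too. Cdkn1a, which encodes the cell cycle inhibitor p21, went from 128 ± 9.49 to 296 ± 4.85 CPM (1.21 on the log2 scale). Of 20 tested genes of mitosis and G2/M, 19 rose and 0 fell, and 20 were called when adjusted over the list alone. The list was higher than other genes (adjusted p = 8.1e-13, and adjusted p = 0.13 with an estimated correlation). Among the 18 tested p53 targets, 14 rose and 0 fell. 15 were called when adjusted over the list alone (adjusted p = 2.6e-11, and adjusted p = 0.033 with an estimated correlation). These included Aen, a p53-induced nuclease (1.19), and Ccng1 (0.57). In DNA replication and G1/S, 11 of 22 genes rose and 1 fell. 12 were called when adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.34 with an estimated correlation). Ccne2, a cyclin of S phase entry, rose by 1.09 and Rrm1, a subunit of ribonucleotide reductase, by 0.44. For cytokinesis and midbody, 9 of 19 rose and 1 fell. 11 were called when adjusted over the list alone (adjusted p = 8.8e-05, and adjusted p = 0.17 with an estimated correlation). Prc1, which bundles the microtubules of the midzone, rose by 0.54 and Ect2, which acts at the cleavage furrow, by 0.38.

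Stress responses and sterol synthesis rose in 1073G as well. Gclc, the rate-limiting enzyme of glutathione synthesis, went from 67.1 ± 1.46 to 122 ± 7.5 CPM (n = 3 each, log2 fold change 0.86), and 9 of 10 NRF2 targets rose while 0 fell. 9 were called when adjusted over the list alone (adjusted p = 4.8e-07, and adjusted p = 0.033 with an estimated correlation). The chaperone Hsp90aa1 went from 434 ± 22.7 to 762 ± 21.7, and 9 of 12 heat shock genes rose and 1 fell. 11 were called when adjusted over the list alone (adjusted p = 4.9e-07, and adjusted p = 0.069 with an estimated correlation). Hspa1b rose by 1.08, although reads of Hspa1a and Hspa1b are hard to tell apart. In the unfolded protein and integrated stress response, 10 of 16 rose and 1 fell, with 12 called when adjusted over the list alone (adjusted p = 1.9e-05, and adjusted p = 0.13 with an estimated correlation), among them Sesn2 (0.66) and the endoplasmic reticulum chaperone Hspa5 (0.45). Interferon-stimulated genes rose in 11 of 24 cases with 0 falls, and 12 were called when adjusted over the list alone (adjusted p = 8.6e-05, and adjusted p = 0.13 with an estimated correlation). Isg15, a ubiquitin-like modifier, went from 3.26 ± 1.12 to 11.3 ± 0.985, and the chemokine Cxcl10 from 3.16 ± 1.34 to 13.6 ± 3.3. Of the cholesterol synthesis genes, 12 of 16 rose and 0 fell. 14 were called when adjusted over the list alone (adjusted p = 7.3e-09, and adjusted p = 0.14 with an estimated correlation). Msmo1, an enzyme of that pathway, rose by 0.77. Immediate early genes rose in 8 of 14 cases and fell in 1, with 9 called when adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.069 with an estimated correlation); Atf3 rose by 0.67 and the phosphatase Dusp1 had a fold change of -0.42. Apoptosis genes rose in 9 of 15 cases and fell in 1. 10 were called when adjusted over the list alone (adjusted p = 0.0078, and adjusted p = 0.11 with an estimated correlation). Those that rose included Pmaip1, which promotes cell death (0.54), and Bcl2l1, which opposes it (0.42). Cytosolic ribosomal proteins rose in 10 of 21 cases with 0 falls, and 15 were called when adjusted over the list alone (adjusted p = 7.2e-06, and adjusted p = 0.38 with an estimated correlation); Rpl4 rose by 0.32, with reads that pseudogenes can share.

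Genes of calcium handling, the sarcomere, fatty acid oxidation and cell junctions fell in 1073G. Atp2a2, the calcium pump of the sarcoplasmic reticulum, went from 6581 ± 192 to 3879 ± 365 CPM (n = 3 each, log2 fold change -0.76), and its inhibitor Pln from 2072 ± 94.5 to 1281 ± 54.1 (-0.69). In calcium handling and excitation, 10 of 18 genes fell and 1 rose. 11 were called when adjusted over the list alone (adjusted p = 2.4e-05, and adjusted p = 0.037 with an estimated correlation). Myh6, the main ventricular myosin heavy chain of the adult rat, went from 14324 ± 966 to 10212 ± 433 (-0.49), and the titin cap protein Tcap had a fold change of -0.71. Of 19 sarcomere genes, 7 fell and 1 rose. 8 were called when adjusted over the list alone (adjusted p = 0.0054, and adjusted p = 0.21 with an estimated correlation). Fatty acid oxidation lost 10 of 18 genes and gained 0. 12 were called when adjusted over the list alone (adjusted p = 1.9e-05, and adjusted p = 0.32 with an estimated correlation). Ppara, the receptor that controls many of them, fell from 63.6 ± 3.23 to 38.4 ± 5.37, and Acadvl had a fold change of -0.39. For nuclear encoded oxidative phosphorylation, 3 of 21 genes fell and 0 rose, with 10 called when adjusted over the list alone (adjusted p = 0.00051, and adjusted p = 0.44 with an estimated correlation); Ndufv1 had a fold change of -0.25. At the intercalated disc and cell junctions, 9 of 14 fell and 1 rose. 10 were called when adjusted over the list alone (adjusted p = 0.0010, and adjusted p = 0.23 with an estimated correlation). The adherens junction protein Ctnna1 went from 1269 ± 28.5 to 1022 ± 39.3 and the desmosome protein Pkp2 from 275 ± 9.52 to 219 ± 12.3.

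Markers of other cell types moved in the same libraries. Macrophage and leukocyte markers fell in 9 of 14 cases and rose in 0, with 11 called when adjusted over the list alone and a median log2 fold change of -0.45 (adjusted p = 1.9e-05, and adjusted p = 0.069 with an estimated correlation). Lyz2, a lysozyme of macrophages, went from 58.0 ± 4.04 to 42.0 ± 0.675 CPM (n = 3 each), and the complement gene C1qb had a fold change of -0.93. Fibroblast markers fell in 4 of 13 cases and rose in 0. 7 were called when adjusted over the list alone (adjusted p = 0.0015, and adjusted p = 0.13 with an estimated correlation). Extracellular matrix genes fell in 8 of 14 cases and rose in 0, with 9 called when adjusted over the list alone (adjusted p = 0.00038, and adjusted p = 0.25 with an estimated correlation); elastin (Eln) had a fold change of -0.43 and Sparc of -0.27. No other list tested was called. Adjusted p values were 0.059 for the fetal and stress program of cardiomyocytes, 0.062 for endothelial, 0.63 for smooth muscle and pericyte, 0.17 for erythroid and 0.32 for Schwann and neural markers. They were 0.22 for centrosome and centriole, 0.22 for SRF/MRTF, 0.45 for YAP/TEAD and 0.63 for TGF-beta targets. For Wnt and planar cell polarity the adjusted p was 0.81, for NF-kB and inflammatory cytokines 0.13 and for glycolysis 0.87, where the median was -0.01 and the test pointed up. Within these lists Acta1 rose by 0.92 and the cytokine Il6 by 2.86. Il6 was low in both groups, at 0.067 to 0.104 CPM in GFP and 0.653 to 0.7 CPM in 1073G.

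Single genes with the largest rises in 1073G included Gdf15, a secreted stress cytokine (2.22 ± 0.25 log2, SE), Resf1, a silencer of retroelements (2.26 ± 0.11), Kitlg, the ligand of the receptor KIT (1.84 ± 0.13), and Oasl, an interferon-induced gene (2.06 ± 0.20). Tmem200c went from 0.0448 ± 0.0656 to 1.64 ± 0.214 CPM (n = 3 each). Among the largest falls, Kcnip2, a subunit of the transient outward potassium channel, went from 91.0 ± 9.01 to 28.3 ± 0.788, and the M-band protein Myom2 from 130.0 ± 7.6 to 41.9 ± 9.38. Klhl33 (-1.73), the sphingosine-1-phosphate phosphatase Sgpp2 (-1.87) and the Wnt agonist Rspo1 (-1.59) fell too. Across all 15152 tested genes, edgeR called 3767, of which 1979 rose and 1788 fell; 242 changed more than 2-fold, 133 of them upward, and the median size of a called change was 0.36 (log2). Libraries of the groups did not overlap for 39.3% of genes, where chance gives 10%. Camera called 20 of 33 lists, and 3 of these calls (p53 targets, NRF2 targets, and calcium handling and excitation) held with an estimated correlation. Mdn1, at 0 in every library of GFP and of 1073S, stood at 3.58, 4.28 and 0.451 CPM in the 1073G libraries. Zeros beside such values in deep libraries can come from how reads were assigned to transcripts, so no fold is given, and the call was lost without any 1 of 7 libraries (adjusted p 0.050 to 0.10).

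In 1073S against GFP, replication genes, p53 targets and interferon-stimulated genes rose, and genes of contraction fell. Ccne2 went from 24.7 ± 0.809 to 97.1 ± 10 CPM (n = 3 libraries each, log2 fold change 1.98), and Mcm3, a subunit of the replicative helicase, from 36.1 ± 1.41 to 93.8 ± 6.72 (1.38). Cdkn1a went to 470.4 ± 20.3 (1.87), Gclc to 288 ± 23.5 (2.10) and Pln down to 889 ± 49.6 (-1.22). Of 22 genes of DNA replication and G1/S, 20 rose and 1 fell, with 22 called when adjusted over the list alone and a median of 0.68 (adjusted p = 7.0e-09, and adjusted p = 0.11 with an estimated correlation). The exception was E2f1, a transcription factor of S phase entry, named after its value was seen (-0.88, adjusted p = 2.5e-05). For mitosis and G2/M, 19 of 20 rose and 0 fell, with 19 called when adjusted over the list alone (adjusted p = 1.3e-08, and adjusted p = 0.20 with an estimated correlation), Ccnb1 reaching 404 ± 9.98. For cytokinesis and midbody, 13 of 19 rose and 2 fell, with 17 called when adjusted over the list alone (adjusted p = 0.00038, and adjusted p = 0.20 with an estimated correlation), including Prc1 (0.54) and Cep55, which recruits the abscission machinery (0.48). Centrosome and centriole genes rose in 9 of 15 cases with 0 falls, and 9 were called when adjusted over the list alone (adjusted p = 0.020, and adjusted p = 0.21 with an estimated correlation). Plk4, the kinase that starts centriole duplication, rose by 0.77 and Sass6, of the centriole cartwheel, by 0.61. The call of this list was lost without 1073S replicate 1 (adjusted p = 0.057).

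Of the p53 targets, 15 of 18 rose and 1 fell in 1073S, with 16 called when adjusted over the list alone and a median of 0.95 (adjusted p = 7.0e-09, and adjusted p = 0.041 with an estimated correlation). Mdm2, the ubiquitin ligase that degrades p53, went from 149.8 ± 5.38 to 369 ± 10.6 CPM (n = 3 each). NRF2 targets rose in 8 of 10 cases with 0 falls and 8 called when adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.039 with an estimated correlation); sulfiredoxin (Srxn1) rose by 1.38 and thioredoxin reductase (Txnrd1) by 0.72. Interferon-stimulated genes rose in 15 of 24 cases with 0 falls and 15 called when adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.087 with an estimated correlation), Isg15 reaching 21.2 ± 1.27. Heat shock genes rose in 10 of 12 cases and fell in 1, with 11 called when adjusted over the list alone (adjusted p = 3.8e-05, and adjusted p = 0.094 with an estimated correlation), and Hsp90aa1 reached 1026 ± 19.6. In the unfolded protein and integrated stress response, 12 of 16 rose and 0 fell, with 12 called when adjusted over the list alone (adjusted p = 6.7e-06, and adjusted p = 0.11 with an estimated correlation), Sesn2 by 1.14. Cholesterol synthesis genes rose in 14 of 16 cases with 0 falls and 14 called when adjusted over the list alone (adjusted p = 1.3e-06, and adjusted p = 0.20 with an estimated correlation). Ribosomal proteins rose in 17 of 21 cases with 0 falls and 18 called when adjusted over the list alone (adjusted p = 1.9e-06, and adjusted p = 0.34 with an estimated correlation). Immediate early genes rose in 10 of 14 cases and fell in 1, with 11 called when adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.083 with an estimated correlation), Jun by 0.91. Apoptosis genes rose in 9 of 15 cases and fell in 2, with 11 called when adjusted over the list alone (adjusted p = 0.0063, and adjusted p = 0.088 with an estimated correlation). The death receptor Fas rose by 1.11. Sesn2 and Fas are also members of the list of p53 targets.

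**Figure D2:**
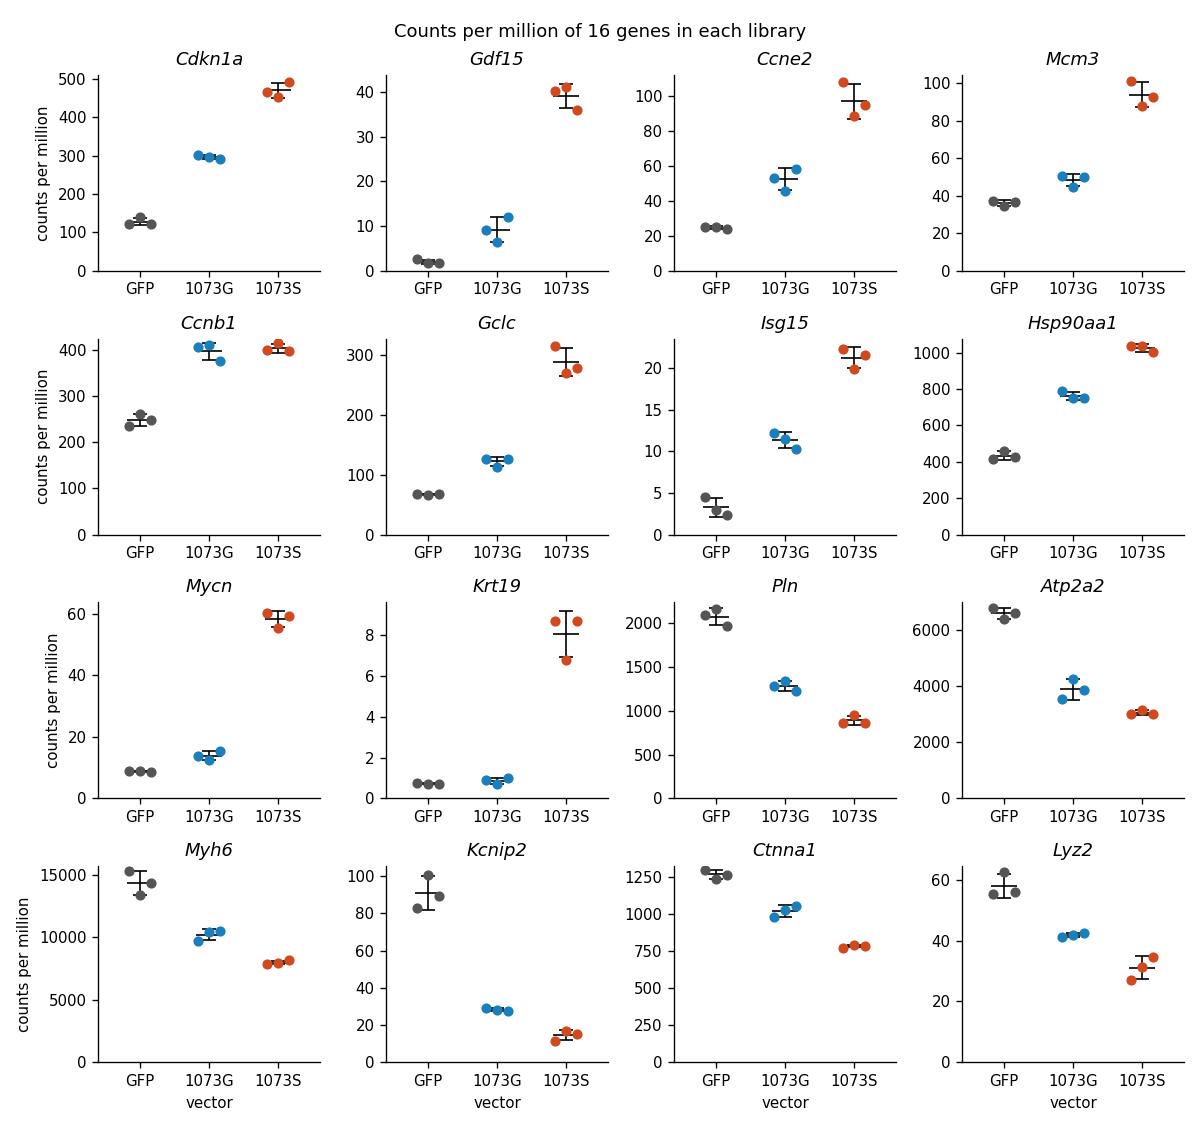
CPM (each axis from 0) of 16 genes in each library, by vector; points are libraries and bars give the mean ± SD of 3. Cdkn1a, Gclc and Isg15 are higher in 1073G than in GFP and higher again in 1073S, while Ccnb1 lies at 397 ± 18.3 and 404 ± 9.98 in the variants and Mycn and Krt19 are highest in 1073S.

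Genes of calcium handling, the sarcomere, fatty acid oxidation, oxidative phosphorylation and cell junctions fell in 1073S. Of 18 genes of calcium handling and excitation, 13 fell and 1 rose, with 16 called when adjusted over the list alone and a median of -0.51 (adjusted p = 5.5e-06, and adjusted p = 0.039 with an estimated correlation). Atp2a2 went to 3050.3 ± 82.9 CPM (n = 3), and the histidine-rich calcium-binding protein Hrc from 62.9 ± 2.75 to 25.3 ± 2.19. Sarcomere genes fell in 15 of 19 cases and rose in 2. 18 were called when adjusted over the list alone (adjusted p = 3.9e-06, and adjusted p = 0.084 with an estimated correlation). Myh6 went to 7971 ± 149, and the Z-disc protein Actn2 from 2488 ± 99.3 to 1762 ± 12.2. Fatty acid oxidation genes fell in 15 of 18 cases with 0 rises and 15 called when adjusted over the list alone (adjusted p = 2.4e-05, and adjusted p = 0.30 with an estimated correlation), Ppara by a fold change of -1.01. Oxidative phosphorylation genes fell in 17 of 21 cases with 0 rises and 19 called when adjusted over the list alone (adjusted p = 2.6e-05, and adjusted p = 0.34 with an estimated correlation), Cox6a2, the muscle form of a cytochrome c oxidase subunit, with -0.47. Junction genes fell in 10 of 14 cases and rose in 1. 11 were called when adjusted over the list alone (adjusted p = 0.0018, and adjusted p = 0.23 with an estimated correlation). Ctnna1 had a fold change of -0.69 and Pkp2 of -0.58, while the gene that rose was Cxadr, the coxsackievirus and adenovirus receptor (0.49).

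Non-myocyte markers fell beside these groups. Macrophage and leukocyte markers fell in 12 of 14 cases and rose in 0, with 12 called when adjusted over the list alone and a median of -0.89 (adjusted p = 5.3e-06, and adjusted p = 0.081 with an estimated correlation). Lyz2 went to 31.1 ± 3.79 CPM (n = 3) and Tyrobp, an adaptor of myeloid receptors, from 7.03 ± 0.438 to 3.22 ± 0.168. Fibroblast markers fell in 8 of 13 cases and rose in 0, with 8 called when adjusted over the list alone and a median of -0.47 (adjusted p = 0.00069, and adjusted p = 0.092 with an estimated correlation). The fibroblast transcription factor Tcf21 had a fold change of -1.16 and lumican (Lum) of -0.73. Extracellular matrix genes fell in 11 of 14 cases and rose in 0, with 11 called when adjusted over the list alone (adjusted p = 0.00015, and adjusted p = 0.21 with an estimated correlation), Col4a1 by a fold change of -0.48. Endothelial markers were not called as a list (adjusted p = 0.074), although 6 of 14 fell and 0 rose. Other lists without a call had adjusted p values of 0.79 for the fetal and stress program (6 rose and 6 fell of 14), 0.45 for SRF/MRTF targets (4 rose and 5 fell of 17) and 0.19 for Wnt and planar cell polarity (6 rose and 2 fell of 18). They were 0.23 for YAP/TEAD and 0.71 for TGF-beta targets, 0.18 for NF-kB and inflammatory cytokines, 0.33 for glycolysis, 0.32 for smooth muscle and pericyte, 0.22 for Schwann and neural and 0.76 for erythroid markers. Within them the glucose transporter Slc2a1 rose by 0.69, and the stress-responsive Ankrd1 had a fold change of -0.89.

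Single genes with large rises in 1073S were Gdf15, which reached 39.1 ± 2.72 CPM against 1.98 ± 0.513 in GFP (n = 3 each), Mx2, an interferon-induced GTPase (0.853 ± 0.47 to 10.2 ± 3.2), the serotonin receptor gene Htr4 (0.185 ± 0.238 to 4.42 ± 0.841) and the neuropeptide Y receptor gene Npy1r (0.0348 ± 0.0603 to 2.76 ± 0.347). Large falls were those of Kcnip2 (91.0 ± 9.01 to 14.4 ± 2.7), Klhl33 (-2.58), the IgE receptor gene Fcer2 (-3.41), the keratin gene Krt7 (-2.38), Nsg2 (-2.27) and Rspo1 (-2.26). Across the 15152 genes edgeR called 7024, of which 3495 rose and 3529 fell; 373 rose and 559 fell more than 2-fold, with a median size of 0.45 (log2). Libraries did not overlap for 56.4% of genes, where chance gives 10%. Camera called 21 of 33 lists, and the calls of p53 targets, NRF2 targets, and calcium handling and excitation held with an estimated correlation. Eda2r, a p53 target at 0 in every GFP library and at 4.39 to 13.5 CPM in 1073S, stood at 7.995, 7.117 and 0 in the 1073G libraries. A 0 of this gene can therefore come from read assignment, so no fold is given, and its call was lost without any 1 of 8 libraries (adjusted p 0.081 to 0.11).

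The direct comparison of 1073S with 1073G asks what differs between the variants, with Shroom3 itself 2.14 (log2) higher in 1073S. DNA replication genes had the smallest adjusted p of the lists with the preset correlation, and the call was lost with an estimated correlation. Mcm3 went from 48.3 ± 3.34 in 1073G to 93.8 ± 6.72 CPM in 1073S (n = 3 libraries each, log2 fold change 0.96 ± 0.07, SE, adjusted p = 1.3e-05), and Ccne2 from 52.4 ± 6.19 to 97.1 ± 10 (0.89). The proto-oncogene Mycn, which drives growth and biosynthesis, rose from 13.9 ± 1.39 to 58.3 ± 2.71 (2.06 ± 0.08, SE, adjusted p = 1.2e-08), and the keratin gene Krt19 from 0.864 ± 0.156 to 8.07 ± 1.11 (3.22 ± 0.19, SE). Of 22 genes of DNA replication and G1/S, 19 rose and 0 fell, with 20 called when adjusted over the list alone and a median of 0.44 (adjusted p = 9.4e-17, and adjusted p = 0.065 with an estimated correlation). Mitosis and G2/M genes were not called (adjusted p = 0.12), with 1 of 20 higher and 1 lower, and neither were cytokinesis and midbody genes (adjusted p = 0.25). Centrosome and centriole genes were higher (3 of 15 rose and 0 fell, with 6 called when adjusted over the list alone; adjusted p = 0.0024, and adjusted p = 0.15 with an estimated correlation), Sass6 by 0.37.

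Stress responses stood higher in 1073S than in 1073G. Gclc rose from 122 ± 7.5 to 288 ± 23.5 CPM (n = 3 each), and 6 of 10 NRF2 targets rose and 0 fell. 8 were called when adjusted over the list alone (adjusted p = 1.6e-06, and adjusted p = 0.030 with an estimated correlation). Cdkn1a rose by 0.67, and of the p53 targets 11 of 18 rose and 1 fell. 13 were called when adjusted over the list alone (adjusted p = 1.2e-09, and adjusted p = 0.032 with an estimated correlation). Interferon-stimulated genes rose in 10 of 24 cases with 0 falls and 13 called when adjusted over the list alone (adjusted p = 1.1e-07, and adjusted p = 0.088 with an estimated correlation); the regulator Irf7 rose by 0.94 and Isg15 by 0.91. In the unfolded protein and integrated stress response 6 of 16 rose and 0 fell, with 9 called when adjusted over the list alone (adjusted p = 1.7e-05, and adjusted p = 0.15 with an estimated correlation), Dnajb9 by 0.30. Heat shock genes rose in 4 of 12 cases and fell in 1, with 8 called when adjusted over the list alone (adjusted p = 0.018, and adjusted p = 0.29 with an estimated correlation), Hsp90aa1 by 0.43. Apoptosis genes rose in 3 of 15 cases with 0 falls and 4 called when adjusted over the list alone (adjusted p = 0.0085, and adjusted p = 0.089 with an estimated correlation), Pmaip1 by 0.34. Ribosomal proteins rose in 2 of 21 cases with 0 falls and 7 called when adjusted over the list alone (adjusted p = 0.00028, and adjusted p = 0.48 with an estimated correlation). Cholesterol synthesis genes rose in 3 of 16 cases with 0 falls and 5 called when adjusted over the list alone (adjusted p = 0.0099, and adjusted p = 0.48 with an estimated correlation), a call lost without 1073G replicate 2 (adjusted p = 0.12). Wnt and planar cell polarity genes rose in 2 of 18 cases with 0 falls and 5 called when adjusted over the list alone (adjusted p = 0.035, and adjusted p = 0.21 with an estimated correlation). Lef1 rose by 1.14. That list's call was lost without 1073G replicate 1 (adjusted p = 0.11) and without 1073S replicate 1 (adjusted p = 0.091).

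**Figure D3:**
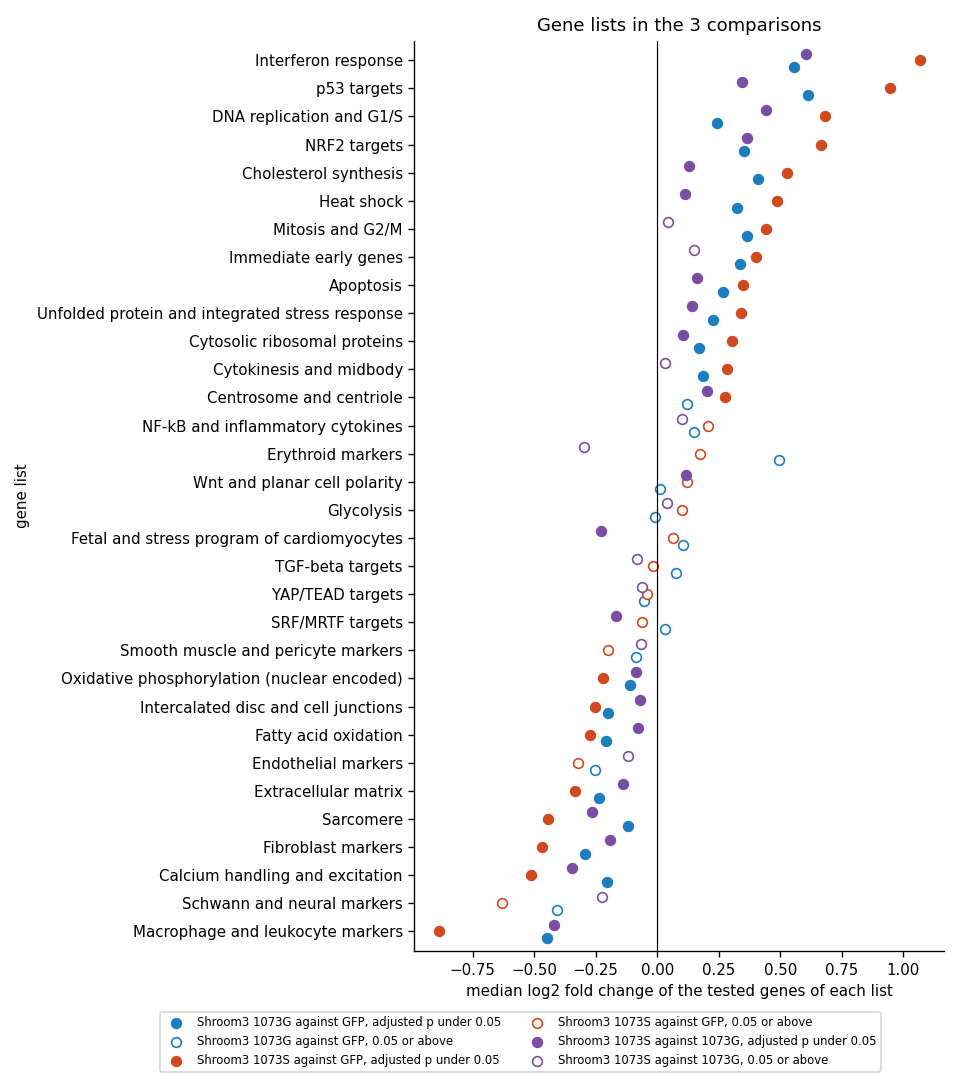
Median log2 fold change (x axis) of the tested genes of each of 32 lists (y axis) in the 3 comparisons of groups; filled points have a camera adjusted p under 0.05 with the preset correlation, open points do not. DNA replication and G1/S lies at 0.25, 0.68 and 0.44 for 1073G against GFP, 1073S against GFP and 1073S against 1073G, and macrophage markers at -0.45, -0.89 and -0.42.

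Contractile genes were lower in 1073S than in 1073G. Of 19 sarcomere genes, 10 fell and 0 rose, with 14 called when adjusted over the list alone and a median of -0.27 (adjusted p = 5.0e-09, and adjusted p = 0.043 with an estimated correlation). Cardiac actin (Actc1) went from 12126 ± 1190.1 to 8554 ± 285 CPM (n = 3 each) and troponin C (Tnnc1) from 643 ± 38.1 to 492 ± 8.17. Calcium handling and excitation genes fell in 9 of 18 cases with 0 rises and 12 called when adjusted over the list alone (adjusted p = 3.0e-06, and adjusted p = 0.030 with an estimated correlation); Pln had a fold change of -0.53 and Casq2, which stores calcium, of -0.39. In the fetal and stress program 7 of 14 fell and 1 rose. 9 were called when adjusted over the list alone (adjusted p = 0.0055, and adjusted p = 0.21 with an estimated correlation). The natriuretic peptide gene Nppa went from 15817 ± 1326 to 12182 ± 736, and the gene that rose was Gdf15 (2.09). SRF/MRTF targets fell in 5 of 17 cases and rose in 1, with 8 called when adjusted over the list alone (adjusted p = 0.00076, and adjusted p = 0.27 with an estimated correlation), smooth muscle actin (Acta2) with -0.59 and Fhl2 with -0.44. Oxidative phosphorylation was called with a median of -0.09, but none of its 21 genes was called alone by edgeR or when adjusted over the list alone (adjusted p = 0.00074, and adjusted p = 0.48 with an estimated correlation). Fatty acid oxidation had 1 fall and 0 rises among 18 genes and 0 called when adjusted over the list alone (adjusted p = 0.0085, and adjusted p = 0.49 with an estimated correlation). Its call was lost without 1073G replicate 2 (adjusted p = 0.17) and without 1073S replicate 1 (adjusted p = 0.094). Junction genes fell in 3 of 14 cases and rose in 1, with 4 called when adjusted over the list alone (adjusted p = 0.039, and adjusted p = 0.48 with an estimated correlation), Ctnna1 with -0.38. That call was lost without 1073G replicate 2 or 3 or 1073S replicate 2 or 3 (adjusted p 0.051 to 0.17).

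Macrophage and leukocyte markers also fell between the variants, in 4 of 14 cases with 0 rises and 6 called when adjusted over the list alone, at a median of -0.42 (adjusted p = 0.00012, and adjusted p = 0.088 with an estimated correlation). Fibroblast markers fell in 2 of 13 cases with 0 rises and 2 called when adjusted over the list alone (adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation), Lum with a log2 fold change of -0.41. Extracellular matrix genes fell in 3 of 14 cases with 0 rises and 6 called when adjusted over the list alone (adjusted p = 0.0072, and adjusted p = 0.40 with an estimated correlation), a call lost without 1073G replicate 3 (adjusted p = 0.097). Further lists without a call had adjusted p values of 0.056 for immediate early genes, 0.11 for glycolysis, 0.14 for TGF-beta and 0.20 for YAP/TEAD targets, and 0.38 for NF-kB and inflammatory cytokines. They were 0.38 for endothelial, 0.25 for smooth muscle and pericyte, 0.24 for Schwann and neural and 0.31 for erythroid markers. Other large single rises were those of Tnfrsf19 (1.65), the homeobox gene Emx2 (1.64) and Enpp2, which makes lysophosphatidic acid (1.56). Large falls were those of the fast muscle myosin gene Myh1 (-1.54) and Nmrk2, a muscle enzyme of NAD synthesis (-1.20). Across all 15152 genes edgeR called 1956, of which 1088 rose and 868 fell; 44 rose and 42 fell more than 2-fold. The count was 1112 without 1073S replicate 1 and, as an alternative added after seeing the data, 1198 with unmatched accessions kept as features. Libraries did not overlap for 31.8% of genes, where chance gives 10%. Camera called 21 of 33 lists, and the calls of p53 targets, NRF2 targets, calcium handling and excitation, and sarcomere held with an estimated correlation.

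Most genes that 1073G changed against GFP changed in the same direction in 1073S, which also changed many others. Of the 1978 genes other than Shroom3 that rose in 1073G, 1866 (94.3%) rose in 1073S too, and of 1788 that fell, 1673 (93.6%) fell too, while 3 genes (H1f2, Itga9 and Vgll4) were called in opposite directions. The shared calls were 53.4% of the 3494 rises and 47.4% of the 3529 falls in 1073S. Independent calls would share 456 rises and 416 falls, a count that leaves the shared GFP libraries out. In 20 simulated datasets with unchanged groups and the same shared GFP libraries, at most 0 rises and 1 fall were shared. Unchanged groups give few calls to share, so neither count shows how much of the sharing came from the common controls. Across 12415 genes above 1 CPM, which are not independent replicates, Pearson's r of the fold changes was 0.844, where the simulations gave a mean of 0.516 from the shared controls alone, and 85.3% of genes had the same sign against a simulated 66.7%. With separate GFP libraries for each variant (1 for a variant and 2 for the other, in 6 ways, a test added after the data were seen), r was 0.609 to 0.680 and 77.0% to 82.0% of genes had the same sign. The simulated values hold for shared controls and are not a reference for these, and no simulation was run with separate controls. For genes called in both, the median ratio of the 1073S to the 1073G fold change was 1.47 (quartiles 1.21 to 1.76). Of the 1955 genes besides Shroom3 called between 1073S and 1073G, 1717 (87.8%) had the 1073G mean between those of GFP and 1073S.

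**Figure D4:**
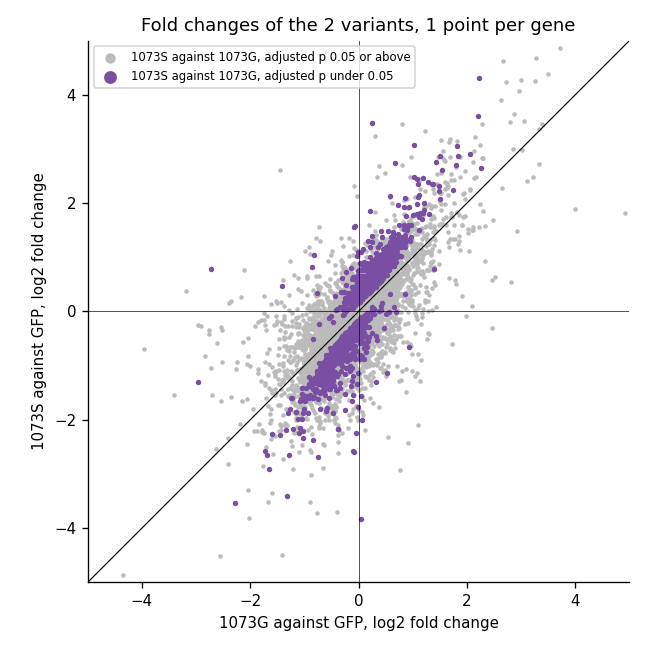
Log2 fold change against GFP of 1073G (x axis) and 1073S (y axis), 1 point for each of 15151 genes without Shroom3, with the line of equal change; purple points have an adjusted p under 0.05 between the variants, and 31 genes lie beyond the axis limit of 5. Most genes lie in the quadrants of equal sign, and the purple points lie on either side of the line.

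The mean of both variants against GFP gave 6369 called genes in edgeR, 3177 higher and 3192 lower, with 244 rises and 327 falls beyond 2-fold. Ccng1, a p53-induced cyclin, rose by 0.73 ± 0.04 (log2, SE, adjusted p = 1.8e-08) and Gclc by 1.48 ± 0.06 (adjusted p = 5.5e-09), while Atp2a2 (-0.94 ± 0.05, adjusted p = 3.3e-08) and Myh6 (-0.67 ± 0.05, adjusted p = 1.9e-07) fell. Camera called 20 of 33 lists, 12 upward and 8 downward, and these were the same 20 as in 1073G against GFP. The smallest adjusted p values were those of mitosis and G2/M (20 of 20 rose, 0 fell; adjusted p = 5.4e-10, and adjusted p = 0.16 with an estimated correlation) and p53 targets (14 of 18 rose, 0 fell; adjusted p = 2.4e-09, and adjusted p = 0.036 with an estimated correlation). NRF2 targets and calcium handling and excitation also held with an estimated correlation (adjusted p = 0.036 and 0.036). Centrosome and centriole genes were not called (adjusted p = 0.053). For glycolysis, with a median of 0.03, and SRF/MRTF targets, with -0.02, the median, the mean and the test did not share 1 sign, and neither list was called (adjusted p = 0.50 and 0.99).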

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

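The comparison of the 1073G mean with the range from GFP to 1073S, its simulation and the fit with unmatched accessions were chosen only after the results were seen; the difference between the variants had been planned. Reads on RefSeq accessions that match no gene in the table used were left out of the comparisons of the report except in the fit that kept them as features. Of 9024 such accessions tested in edgeR, 158 were higher in 1073G than in GFP, 440 were higher in 1073S than in GFP and 69 were higher in 1073S than in 1073G, while 150, 458 and 78 were lower. These were 3.41%, 9.95% and 1.63% of the accessions, against 18.1%, 39.1% and 7.91% of the genes called in the same fit. No gene is named for them, since the table does not pair them with genes.

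The genes H1f2, Itga9 and Vgll4 stood out because each was called against GFP upward in 1 variant and downward in the other. H1f2, a linker histone gene whose reads near-identical histone genes can share, had a log2 fold change of 0.19 in 1073G (edgeR adjusted p = 0.042). In 1073S it had -0.28 (adjusted p = 0.0020). Itga9, an integrin subunit gene, had -0.24 (adjusted p = 0.020) and 0.25 (adjusted p = 0.0095). Vgll4, a cofactor of TEAD factors, had -0.24 (adjusted p = 0.037) and 0.20 (adjusted p = 0.047). Between the variants the edgeR adjusted p values were 0.00051 for H1f2, 0.00076 for Itga9 and 0.0027 for Vgll4. The comparison of the variants does not by itself test opposite movement against GFP.

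These genes belong to 42 genes called between 1073S and 1073G whose 1073G mean lay outside the range from GFP to 1073S and was itself called against GFP, in 22 cases above and in 20 below. A monotone response to the level of Shroom3 gives none beyond noise, and 20 simulated datasets with every 1073G mean held inside the range gave a median of 18.5 and at most 25. The first bound, more than that highest count, was passed by 42, but it was replaced after the result was seen by 2 times the highest count, because the simulation leaves inside the range the genes whose measured mean fell inside it by chance and so can give too few; 42 does not pass that bound. Whether these genes depart from a monotone response therefore stays open. For the 87.8% of calls with 1073G in between, variant and Shroom3 level changed together, so that a response to level may give the same values and an effect of the variant cannot be told apart from it. The dose of vector in each group is not known, so an effect of dose cannot be told apart from these either.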

How the results depend on the processing

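Keeping unmatched accessions as features was chosen only after seeing the data; the other alternatives were fixed before. No result reversed under any alternative. Of the counts of genes, 61 of 63 alternative values stayed within 1.5 times the reported count. The exceptions were in 1073S against 1073G, 1198 genes with unmatched accessions kept and 1112 without 1073S replicate 1; leaving out each library in turn gave 1112 to 2021 there, 2967 to 3706 in 1073G against GFP, 6030 to 7041 in 1073S against GFP and 5404 to 6252 for both variants, and 2812 to 3346 shared calls. Leaving out a library lowers the number of samples, and the cause of the low count without that library was not tested further. Fewer lists were called with an estimated correlation between genes. The counts were 3, 3, 4 and 3 in 1073G against GFP, 1073S against GFP, 1073S against 1073G and both variants against GFP. Only that setting of camera differed between the runs, so the lower counts follow from it. The size of the estimated correlations is not given, and which effect of the setting lowered the counts was not tested. In place of camera, fry called 24, 25, 16 and 25 lists; in 1073S against 1073G it lost the calls of fatty acid oxidation, oxidative phosphorylation, junctions, extracellular matrix, cholesterol synthesis and ribosomal proteins (adjusted p 0.066 to 0.19). Leaving out libraries gave 20 to 22 lists, 20 to 21, 20 to 22 and 20 to 22. Among single lists, 1717 of 1848 values kept their side of the threshold, 86 lost it and 45 gained it. For Shroom3 all 63 values were past the threshold in the same direction. For 407 results on genes eligible to be named, 6141 of 6415 values were past the threshold in the same direction and 274 were not; none of these changed sign. DESeq2 called 4299, 7227, 2660 and 6614 genes. The replicate number as a block gave 3688, 6945, 1887 and 6338, although nothing pairs the libraries. Depth limits genes at or below about 0.0486 CPM, where a count of 0 allows up to 3 reads.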

Other observations

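The lists in this part and the tests on cell types and on replication against mitosis were chosen only after the fold changes were seen; the counts over other splits of the libraries had been planned. P values of the 6 added lists were adjusted over those lists alone and cannot be ranked against values adjusted over the 33 lists. Genes that charge tRNAs and make serine were higher with both variants. All 19 tested genes of the list of aminoacyl-tRNA synthetases and serine synthesis rose in 1073G, and all 19 in 1073S, with median log2 fold changes of 0.30 and 0.57 (adjusted p = 5.5e-14, and adjusted p = 0.0062 with an estimated correlation in 1073G; adjusted p = 2.6e-14, and adjusted p = 0.0058 with an estimated correlation in 1073S). Between the variants 16 of 19 were higher in 1073S and 0 lower (adjusted p = 5.9e-17, and adjusted p = 0.0038 with an estimated correlation). Mthfd2, a mitochondrial folate enzyme, rose by 0.78 and 1.19, Psat1, of serine synthesis, by 0.45 and 0.96, and the tyrosyl-tRNA synthetase Yars1 by 0.55 and 0.95.

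Tricarboxylic acid cycle genes fell in 4 of 16 cases in 1073G (adjusted p = 0.00066, and adjusted p = 0.22 with an estimated correlation) and in 12 in 1073S (adjusted p = 0.00070, and adjusted p = 0.17 with an estimated correlation), with 0 rises, and 1 of them, Idh3a, fell between the variants (-0.14; adjusted p = 0.045, and adjusted p = 0.39 with an estimated correlation for the list). Genes of creatine, adenylate and phosphate shuttles were not called as a list (adjusted p = 0.30 in 1073G, 0.64 in 1073S and 0.83 between the variants). In 1073S that list's median was 0.01 while the test pointed down, and the muscle creatine kinase gene Ckm had a log2 fold change of -0.59.

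In the comparisons of 3 libraries with 3, the design gives only 10 splits, too few for a share under 0.05; the real splits gave 3767 genes in 1073G against GFP, 7024 in 1073S against GFP and 1956 in 1073S against 1073G, each as the 1 split that large, and the highest others gave 0, 1 and 1. For both variants against GFP, 1 of 84 splits, the real one with 5327 genes in a fit of 2 groups, gave as many, which argues against a random grouping of these libraries but not against differences between cultures. The highest other gave 3162 and set the 1073S libraries against the rest.

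Macrophage (adjusted p = 5.3e-06, and adjusted p = 0.081 with an estimated correlation) and fibroblast markers (adjusted p = 0.00069, and adjusted p = 0.092 with an estimated correlation) fell in 1073S against GFP, and neither call held with that estimate. A lower share of all non-myocytes alike would move markers that only those cells express by 1 amount. The medians were -0.89 for macrophage markers and -0.28 for endothelial and mural markers (permutation p = 5.0e-05, 100000 permutations, genes not independent). Of the 10 smooth muscle and pericyte (mural) markers, 4 fell and 2 rose. Whether other cells expressed the listed genes was not measured, so this difference does not decide the question. Fewer macrophages may account for their part: 12 of 14 macrophage markers fell past the threshold and none rose, with quartiles of -1.26 to -0.76, and Lyz2, the most abundant of those named, went from 58.0 ± 4.04 to 31.1 ± 3.79 CPM (n = 3 each). Lower expression per macrophage stays open.

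Replication genes rose in 1073S over 1073G (adjusted p = 9.4e-17, and adjusted p = 0.065 with an estimated correlation). A rise of the whole cell cycle program would move replication and mitosis genes alike, but their medians were 0.44 over 22 genes and 0.05 over 20 genes (permutation p = 5.0e-05, two-sided, 100000 permutations, genes not independent). Whether more cells stood in S phase or the genes were higher per cell was not measured.

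The rise of Mycn led to the hypothesis that a list of ribosome biogenesis genes and other MYC-bound genes rose with it. MYC binding was not measured here. Of the 22 tested genes of this list, which include Odc1 and Cad, 19 rose in 1073S against 1073G, with a median of 0.45. The camera adjusted p was 1.1e-18, although the call was lost with an estimated correlation (adjusted p = 0.053). Against GFP, 15 rose in 1073G (adjusted p = 1.2e-08, and adjusted p = 0.16 with an estimated correlation) and 22 in 1073S (adjusted p = 1.7e-13, and adjusted p = 0.11 with an estimated correlation), among them Nop56 (1.11) and Nolc1 (1.03). This is consistent with Mycn as a candidate cause, but other regulators of these genes were not tested.

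Axin2, Sp5 and Tnfrsf19, targets of beta-catenin signalling, rose in 1073S against GFP, named after their values were seen. Axin2 went from 0.103 ± 0.156 to 1.23 ± 0.133 CPM (n = 3 each, adjusted p = 0.0070), Tnfrsf19 from 2.05 ± 0.0761 to 6.08 ± 0.279, and Sp5 was at 0 in every GFP library and at 0.179 to 0.440 CPM in 1073S. The hypothesis of a wider rise was tested on 9 other targets, of which 5 rose and 0 fell (camera adjusted p = 0.034, and adjusted p = 0.17 with an estimated correlation), so any rise of this pathway may be limited to some targets. In 1073G the list was not called (adjusted p = 0.16), and neither was it between the variants (adjusted p = 0.056). These targets are not a fresh set, since Lef1, Nkd1, Rnf43 and Znrf3 had been tested in the fixed list of Wnt and planar cell polarity. As given above, that fixed list was not called in 1073S against GFP but was called between the variants.

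Sarcomere (adjusted p = 3.9e-06, and adjusted p = 0.084 with an estimated correlation) and calcium handling genes (adjusted p = 5.5e-06, and adjusted p = 0.039 with an estimated correlation) fell in 1073S against GFP, and only the second call held with that estimate. A lower share of cardiomyocytes alone would raise the markers of other cell types, but 46 of 51 macrophage, fibroblast, endothelial and mural markers were below 0 (exact sign test p = 2.3e-09, two-sided, over genes that are not independent). These included all 14 macrophage and all 13 fibroblast markers, so the pooled p value rests in part on falls already seen. Of the endothelial and mural markers 19 of 24 were below 0, and neither of those lists was called. Another candidate explanation is lower expression of cardiac transcription factors. Of 17 such genes, 11 fell and 1 rose (camera adjusted p = 0.0033, and adjusted p = 0.13 with an estimated correlation), with Irx4 at -0.68, Gata4 at -0.43 and Hand2, which rose, at 0.38 (log2). In 1073G 9 fell (adjusted p = 0.00024, and adjusted p = 0.090 with an estimated correlation), and between the variants the list was not called (adjusted p = 0.13). Order in time was not measured, so the factors could also follow the fall.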
